A study of Mus musculus with 10 samples.

How the data were processed

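Lung endothelial cells of adult C57BL/6 mice were profiled by droplet single-cell RNA sequencing (10x 3' chemistry, version 3.1) in 10 libraries. Mice had received tamoxifen to switch on tdTomato in cells expressing apelin (Apln), and tdTomato-positive cells and endothelial cells were sorted by FACS. The control genotype carried the reporter alone, and in the Kitl-deleted genotype the gene of Kit ligand (Kitl, stem cell factor) was also deleted in Apln-expressing cells. Each genotype had 1 library untreated, 1 at 2 weeks and 1 at 4 weeks after bleomycin, 1 early after removal of lung tissue by unilateral pneumonectomy and 1 at 4 weeks after pneumonectomy. The early pneumonectomy libraries are called 1 week in their titles and 2 weeks in the treatment labels, and the conflict could not be settled. The exon of Kitl that was deleted was not given in the sources used here.

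The submitters' processing notes name Cell Ranger 3.0.0, Seurat 4.0.4 and the mm10 build. The deposited values are natural logarithms (ln) of 1 plus UMIs per 10000 in each cell: exp(value) minus 1 summed to 10000 in every cell, and dividing by the smallest step of each cell gave whole UMI counts for 100% of the 120966066 values above 0 (tolerance 0.01 UMI). The files held 40066 cells and 359571008 UMIs. The untreated and bleomycin files listed 19110 genes and cells with 901 to 4999 detected genes, whereas the pneumonectomy files listed 19518 genes and cells with 1001 to 5998 detected genes, so the authors made 2 file sets with different cell filters. Mitochondrial transcripts stayed at or below 10.0% in every cell. The 18634 genes present in all 10 files were used. Bleomycin and untreated libraries share a file set, but pneumonectomy can be compared with untreated only across file sets, where file set and condition coincide.

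Cells were clustered with scanpy 1.11.5 (Leiden resolution 1.0, igraph 0.11.9, 2000 highly variable genes, 30 principal components, 15 neighbours, seed 0), with no integration since library and group coincide. Clusters were named from 23 fixed marker lists by the mean log2 fold of each list's markers over the other cells of the same libraries, with at least 20 cells. A name was kept if the 10 leading genes of the cluster held at least as many markers of that class as of any other endothelial class. This was 0 and 0 for the systemic-like cluster, whose name rests on the mean fold alone (1.82). The minimum mean fold of 0.5 for a name was set after the clusters had been seen, and 2 clusters stayed unnamed under it. All 13 clusters counted as endothelial. The named classes are written as aerocyte-like (aCap-like), general capillary-like (gCap-like), venous-like and systemic-like, since the clusters are largely specific to libraries. Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 was used.

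UMIs were averaged over the cells of a library with equal weight per cell and expressed as CPM, with UMIs as the counts. The log2 of the mean plus 5 CPM was fitted in limma 3.58.1 (R 4.3.3, intensity trend) with condition and genotype as additive terms over the 8360 genes with a mean of at least 10 CPM. With 1 library per group, the fit had 4 residual degrees of freedom, and its error was the spread between genotypes across conditions. The p-values measure only the spread between these libraries, cells were not treated as replicates, and an effect of a single treatment that differs between genotypes could not be tested in this fit. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of 29 fixed gene lists, 26 had at least 3 members in the fit and were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the 26 lists of each effect. The immune cell, mesenchymal, and erythroid and platelet spillover lists had too few members in the fit. Fry values are printed for only some of the lists, and each printed one was under 0.05. They are a selection and do not show how fry came out for the other lists. Medians of lists within 1 library pair were ranked among 10000 random lists matched over 10 bins of expression, as a description only. Simulated data were made from these libraries. Of 100 genes each raised or lowered by log2 1 and by log2 2, 97 and 98 were recovered for bleomycin at 2 weeks. There 7 of 8143 unchanged genes were called, and for Kitl deletion 99 and 99 of 100 were recovered, with 15 called. The simulated noise took the fitted spread around additive means and was independent between genes and libraries. These shares thus do not cover spread that the real libraries have in common, and they are not a detection rate for the real fit. In the real fit Cyp1a1, at log2 -1.84, did not pass at 2 weeks of bleomycin.

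The comparisons, tests, alternatives and gene lists were chosen before the data were examined, except where the text says otherwise. The genes named for each effect were the 10 highest and 10 lowest log2 differences among called genes with the same sign in both genotypes, or in at least 4 of 5 conditions for Kitl deletion. Places left over were filled with genes at a mean of at least 20 CPM that had the same sign but had not passed the test. Mitochondrially encoded, ribosomal protein, predicted, haemoglobin, immunoglobulin, T cell receptor and sex-linked marker genes were left out of this ranking. Kitl, Kit, Apln, Aplnr, Xist, Ddx3y and tdTomato were named in every case, as were up to 4 members of each gene list. Within single conditions the 5 highest and 5 lowest genes of each pair were taken. Other genes given in the text were chosen after their values were seen. Coordinates came from GENCODE release M21 for mm10, counted from 1, which held 97 of the 98 genes looked up.

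Shares of cells have exact Clopper-Pearson 95% intervals that cover counting error only. Shares were compared between genotypes by a two-sided exact permutation test that swapped genotype within each condition, whose smallest possible p over 5 pairs is 0.063. For proliferating cells, each cell was thinned at random to 2000 UMIs, since libraries differed in depth, and cells with fewer UMIs were left out. Alternatives covered the pseudocount, the expression filter, the scaling, the averaging, the cells, the clustering and each library left out in turn. A term that lets the genotype difference vary between the file sets, the fit without unnamed clusters, the fit without the control untreated and bleomycin libraries, and tests of Kitl deletion within each file set were added after the data had been seen. Doublets were scored with Scrublet as included in scanpy at an expected rate of 6%, which called too few cells to serve as a removal step.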

Results

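The 10 libraries held 2765 to 5464 lung endothelial cells each, with 25959397 to 46583955 UMIs per library. Median depth was 5540 to 11733 UMIs and 2289 to 3700 genes per cell, and the median mitochondrial share was 3.83 to 5.22%. A total of 3 UMIs in a library corresponds to 0.0644 to 0.116 CPM, which is the level that a count of 0 allows. The female-expressed Xist was at or below 0.17 CPM and the Y-linked Ddx3y at 70.8 to 132 CPM in every library. The alveolar surfactant transcript Sftpc reached 3.61 to 29.3 CPM and the club cell transcript Scgb1a1 8.44 to 120 CPM. No group had a second library.

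The first question was what deletion of Kitl in Apln-expressing cells did to Kitl itself. Kitl, the ligand of the Kit receptor, lies on chromosome 10 (mm10, 100015630 to 100100416, plus strand). It fell from 1378 ± 123 CPM in control libraries to 430 ± 47.0 in Kitl-deleted libraries (SD, n = 5 libraries each), 31.2% of control, with a range of 29.8 to 32.2% over the 5 conditions. The limma log2 difference was -1.67 ± 0.06 (SE, adjusted p = 7.3e-05), lower in 5 of 5 conditions. The loss lay mainly in aCap-like cells, the aerocytes of the alveolar capillary, where Kitl fell from 2301 ± 199 to 545 ± 52.5 CPM (log2 -2.07 ± 0.09, limma adjusted p = 5.2e-05). In gCap-like cells, the general capillary cells, Kitl was 358 ± 68.2 and 255 ± 48.5 CPM (log2 -0.48 ± 0.13) and did not pass the test (limma adjusted p = 0.24). Since 3' reads of a deleted gene can remain, these values give transcript levels and not protein.

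Kit, the receptor of Kit ligand on chromosome 5 (75574916 to 75656722, plus strand), was carried by gCap-like cells. Its level there was 463 ± 36.6 CPM in control and 609 ± 55.5 in Kitl-deleted libraries (SD, n = 5), higher in 5 of 5 conditions. That difference did not pass the test (log2 0.39 ± 0.10, limma adjusted p = 0.24), and with the file set term its adjusted p was 0.014. In aCap-like cells Kit stayed between 2.17 and 7.0 CPM. The tdTomato transcript was at 1744 to 2617 CPM in control libraries and 1206 to 2861 in Kitl-deleted libraries, with no difference past the test (limma adjusted p = 0.31). It was mainly in aCap-like cells, at 3104 against 426 CPM in gCap-like cells of the control untreated library. In the Kitl-deleted early pneumonectomy library gCap-like cells reached 1545 CPM. Apln (chromosome X, 48025146 to 48034853, minus strand) was at 0.62 to 3.88 CPM in all libraries. Its receptor Aplnr (chromosome 2, 85136225 to 85139923, plus strand) was at 32.9 to 81.1 CPM, and at 60.9 to 175 CPM in gCap-like cells.

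**Figure D1:**
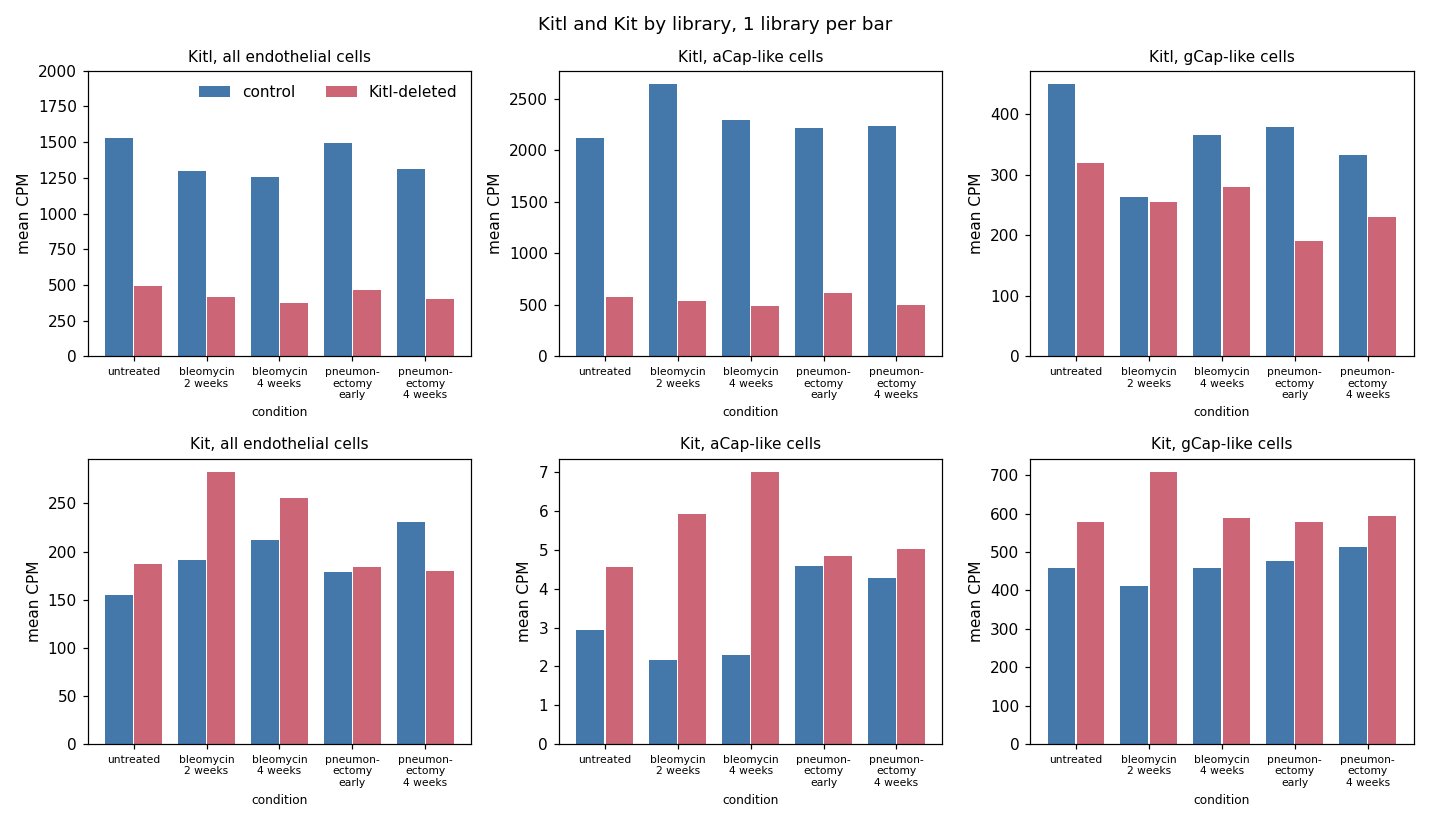
Mean level in CPM (y axes) of Kitl (top) and Kit (bottom) in all endothelial, aCap-like and gCap-like cells, by condition (x axes) and genotype, with 1 library per bar and no error bars. Kitl was lower in each Kitl-deleted library, with aCap-like means of 2301 and 545 CPM in the 2 genotypes, and gCap-like Kit was higher in each Kitl-deleted library.

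Across all 8360 genes, 2 passed the test for Kitl deletion, Kitl and Hebp1, and both were lower. Hebp1, which encodes a heme-binding protein, lies on chromosome 6 (135137522 to 135198022, minus strand) and fell from 143 ± 56.4 to 6.35 ± 0.75 CPM (SD, n = 5; log2 -3.58 ± 0.25 SE, limma adjusted p = 0.0049). It was lower in every pair, at 2.95 to 12.3% of control. Its mean was 3.67% of control in gCap-like and 6.37% in aCap-like cells, whereas Kitl kept 72.9% in gCap-like cells. Whether the loss of Hebp1 follows from the loss of Kitl was not tested. The lowest genes that did not pass were Fam107a (log2 -1.66, adjusted p = 0.095), the clock output factor Tef (-1.61), the natriuretic peptide receptor Npr3 (-1.43), the MHC class II invariant chain Cd74 (-1.43), the glucocorticoid target Tsc22d3 (-1.32), the hyaluronan receptor Lyve1 (-1.28), Tspan4 (-1.06) and the laminin Lama5 (-1.02). The highest that did not pass were AY036118 (2.45), the tetraspanin Cd81 (2.37, adjusted p = 0.11), the mitochondrial leucyl-tRNA synthetase Lars2 (1.98), Ifi27l2a (1.10), Fndc1 (0.82), the urokinase Plau (0.79), Col12a1 (0.76), Slfn2 (0.71), Rprml (0.68) and Ifi203 (0.65). Cd81 was at 86.9 to 494 CPM in control and 526 to 1301 in Kitl-deleted libraries. In all, 2111 genes had an unadjusted p under 0.05. Without either early pneumonectomy library 35 genes were higher and 74 lower (109 in all). Within aCap-like cells alone 5 genes passed and all were lower: Hebp1 (-3.54), Kitl, the kinase Pim3 (-0.995), the lipoprotein lipase anchor Gpihbp1 (-0.92) and Lyve1 (-0.89). Within gCap-like cells alone Hebp1 passed (-3.75, limma adjusted p = 0.015).

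The count for Kitl deletion depended on the file set. With a file set term, added after the data had been seen, 711 genes were higher and 1709 lower. Within the untreated and bleomycin files 1065 were higher and 2388 lower, and within the pneumonectomy files 2 were higher and 2 lower. The 4 genes within the pneumonectomy files were Mgp, the matrix Gla protein that inhibits calcification (log2 1.96, limma adjusted p = 0.013), the MHC class I activator Nlrc5 (0.91, adjusted p = 0.049), Kitl (-1.68, adjusted p = 5.1e-04) and Hebp1 (-4.00, adjusted p = 0.013). The 3 control untreated and bleomycin libraries stood apart from the other 7 on the first principal component (41.7% of variance). Without them the Kitl deletion contrast rests on the pneumonectomy pairs alone, so no count is given for that fit. In these 3 libraries the clock repressor Nr1d1 (chromosome 11, 98767932 to 98775333, minus strand) was at 101 to 123 CPM against 0.807 to 9.52 in the other 7, Tsc22d3 at 328 to 626 against 84.6 to 219, and Lars2 at 151 to 167 against 972 to 1561. The same split holds the rRNA-rich transcript Gm42418, at 3086 to 3312 against 30560 to 74110 CPM.

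Several gene lists shifted with Kitl deletion under camera with the preset correlation, and none of the calls held with an estimated correlation. In the p53 and DNA damage list all 19 members were lower (median log2 -0.43, 13 past the threshold adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.78 with an estimated correlation). Its lowest members were Sesn2 (-0.96), the p53-induced death receptor Eda2r (-0.78), cyclin G1 (Ccng1, -0.72) and the nuclease Aen (-0.69). The MHC class II list was lower in 7 of 7 members (median -0.66, 6 adjusted over the list alone, camera adjusted p = 0.0045, adjusted p = 0.78 with an estimated correlation), with H2-Aa at -0.90 and H2-Eb1 at -0.89. Within gCap-like cells alone the median was -0.57, with 7 of 7 lower (camera adjusted p = 0.044, adjusted p = 0.78 with an estimated correlation). Cd74 was higher in gCap-like than in aCap-like cells in all 10 libraries, and the gCap-like share was smaller in the Kitl-deleted library in 5 of 5 conditions. The shear and quiescence list was lower in 11 of 11 members (median -0.30, 6 adjusted over the list alone, camera adjusted p = 0.0045, adjusted p = 0.78 with an estimated correlation), with the cyclooxygenase Ptgs1 at -0.86, Timp3 at -0.63, Foxo3 at -0.55 and the flow-induced factor Klf2 at -0.52. The hypoxia and glycolysis list was lower in 17 of 18 members (median -0.28, 5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0081, adjusted p = 0.78 with an estimated correlation), with Ndrg1 at -0.83 and Pfkfb3 at -0.73. The proliferation list was lower in 7 of 7 members (median -0.22, 4 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.78 with an estimated correlation), and fry for direction gave an adjusted p of 0.027. Its lowest members were the tubulin Tubb5 (-0.48) and the replication factor Mcm3 (-0.37). The interferon list was higher in 21 of 23 members (median 0.15, 1 adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.78 with an estimated correlation), with Ifi44 at 0.54, Rsad2 at 0.49 and Isg15 at 0.43. No member of these 6 lists passed over all genes. The p53 medians were -0.83, -0.72 and -0.81 in the untreated, 2-week and 4-week bleomycin pairs, and 0.06 and -0.004 in the early and 4-week pneumonectomy pairs. The MHC class II medians were -1.25, -1.19 and -0.58, then 0.20 and -0.81. The proliferation medians were negative in each pair, from -0.38 to -0.14. In the same order the shear and quiescence medians were -0.465, -0.595 and -0.52, then 0.012 and 0.022, with 6 of 11 members higher in both pneumonectomy pairs. The hypoxia medians were -0.246, -0.757 and -0.255, then -0.026 and -0.227. The interferon medians were 0.27, 0.22 and 0.107, then -0.069 with 16 of 23 members lower, and 0.354.

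Within single conditions the genotypes were compared by values alone, with 1 library on each side and no test. In the untreated pair AY036118 was at 283 CPM in control and 4602 in Kitl-deleted cells, Lars2 at 151 and 1504, the linker histone Hist1h1e at 27.6 and 160.5, the BDNF receptor Ntrk2 at 8.61 and 31.4, and Fndc1 at 45.3 and 118. The lowest were Nr1d1 (113 and 3.04), Cd74 (98.2 and 8.05), Tef (62.3 and 6.31), Nr1d2 (65.5 and 7.15) and Npr3 (270.0 and 45.0). At 2 weeks of bleomycin the retinoic acid hydroxylase Cyp26b1 was at 4.34 and 87.0 CPM and Cd81 at 120 and 1044, beside AY036118, Lars2 and Hist1h1e. The lowest there were the metallothionein Mt1 (72.5 and 1.44), Nr1d1, Hebp1, Dbp and Fkbp5. At 4 weeks of bleomycin the highest were AY036118, Lars2, Hist1h1e, the Wnt receptor Fzd6 (5.56 and 41.0) and the tip cell marker Esm1 (8.92 and 32.3). The lowest were Hebp1, Nr1d1, Zbtb16 (375 and 37.7), Dbp and Fam107a (71.1 and 7.23).

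In the early pneumonectomy pair Cd81 was at 86.9 CPM in control and 1301 in Kitl-deleted cells, Col3a1 at 3.47 and 60.7, Mgp at 25.8 and 126, the galectin Lgals1 at 10.9 and 33.9 and the bradykinin receptor Bdkrb2 at 41.0 and 94.7. The fibroblast transcripts Col1a1, Col1a2 and Dcn stood at 33.9, 28.3 and 30.2 CPM in that Kitl-deleted library, against at most 3.45, 4.08 and 24.4 elsewhere. The lowest were Hebp1 (177 and 7.10), Scgb1a1 (60.7 and 13.7), Kitl, Lama5 (33.5 and 13.6) and Arsj (36.9 and 15.3). At 4 weeks after pneumonectomy the highest were Gdpd3 (2.17 and 147.5), Cd81 (90.1 and 1266), Scgb1a1 (20.03 and 119.6), Mgp (17.2 and 73.9) and the heat shock gene Hspa1b (26.1 and 102). The lowest were Hebp1 (187.5 and 6.26), the growth factor Fgf1 (144 and 34.0), Kitl, Armcx4 (111 and 31.4) and Lama5 (37.0 and 8.69).

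The next question was whether Kitl deletion went with a change in the mix of capillary cells within the sorted gate of tdTomato-positive and endothelial cells. The aCap-like share (clusters 0, 2, 4, 5 and 8) was larger in the Kitl-deleted library in 5 of 5 conditions, by 8.14 ± 7.65 percentage points (SD, n = 5 pairs, range 1.23 to 17.7). The gCap-like share (clusters 3, 7, 10 and 11) was smaller in 5 of 5, with a mean difference of -7.46 ± 4.62 points (range -15.1 to -2.75). Both gave an exact permutation p of 0.063, the smallest that 5 pairs allow, and an adjusted p of 0.156, so the design could not reach 0.05. At 2 weeks of bleomycin the aCap-like share was 35.7% in control (95% interval 34.0 to 37.4) and 53.4% in Kitl-deleted cells (52.1 to 54.7). Cluster 4 (3192 cells) was only just above the minimum marker fold (0.545) and drew 36.9% of its cells from that Kitl-deleted library. At Leiden 0.5, where the lowest aCap-like fold was 1.118, the mean aCap-like difference was 8.31 points. At 4 weeks after pneumonectomy it was 51.4% (49.9 to 52.9) and 66.3% (64.6 to 68.0), while the gCap-like share was 43.6% (42.1 to 45.0) and 28.4% (26.8 to 30.1). The untreated aCap-like shares were 64.4% and 66.3%. The systemic-like cells of cluster 12 (972 cells) differed by 0.252 ± 1.03 points (exact permutation p = 0.625, n = 5 pairs), and the venous-like cells of cluster 9 (370 cells) by -0.218 ± 0.539 points (exact permutation p = 0.375, n = 5 pairs). Clusters 1 and 6, kept out of the named classes by the minimum marker fold, held 0.352, 15.3, 7.05, 1.39 and 0.288% of control cells in the order untreated, bleomycin 2 and 4 weeks, pneumonectomy early and 4 weeks. They held 1.498, 6.79, 10.8, 0.975 and 0.858% of Kitl-deleted cells (exact permutation p = 0.938 between genotypes, n = 5 pairs). The classes are built from different clusters in different libraries, and each share is a share of the sorted cells, not of the lung.

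**Figure D2:**
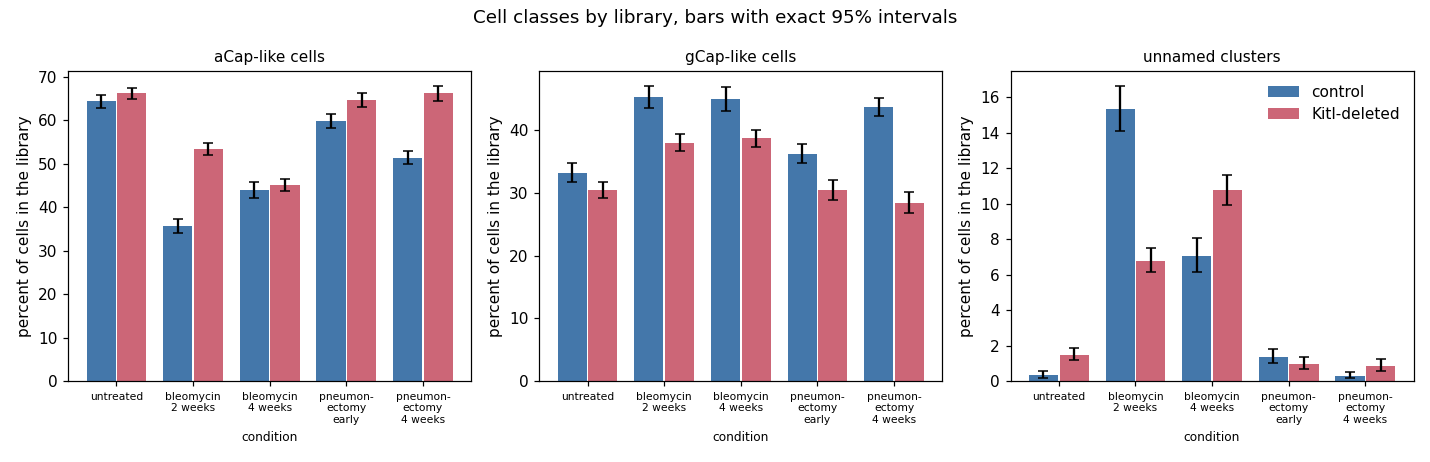
Share of cells in the library (y axes, percent) in aCap-like clusters, gCap-like clusters and the unnamed clusters by condition (x axes) and genotype, with 1 library per bar and exact 95% Clopper-Pearson intervals as error bars. The aCap-like bar was taller in Kitl-deleted cells in each of the 5 conditions, and the unnamed clusters were largest in the 4 bleomycin libraries.

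Bleomycin injures the lung and leads to fibrosis, and the labels ask how it changed lung endothelial cells. At 2 weeks, 43 genes rose and 5 fell against untreated libraries of the same file set (limma, 8360 genes). Ankrd37, a target of hypoxia-inducible factor on chromosome 8 (45996902 to 46005707, minus strand), rose most, from 13.5 to 219.8 CPM in control and from 12.5 to 84.8 in Kitl-deleted cells (log2 2.98 ± 0.35 SE, adjusted p = 0.032). The matricellular genes Sparc (chromosome 11, 55394500 to 55423183, minus strand; log2 1.76 ± 0.15, adjusted p = 0.023) and Sparcl1 (2.68 ± 0.38, adjusted p = 0.037) rose with it. Sparc went from 332 to 1321 CPM in control and from 306 to 903 in Kitl-deleted cells. In the control and Kitl-deleted 2-week libraries Sparcl1 was at 1308 and 789 CPM in gCap-like and 26.6 and 23.6 in aCap-like cells. The aCap-like share was smaller there than untreated, so these means and the list medians below also hold a shift of the class mix. Without the unnamed clusters, which Ankrd37 leads, 38 genes were called. The other risers were Plac8 (2.64 ± 0.33), the Rac exchange factor Tiam1 (2.63 ± 0.36), Clca3a1 (2.32 ± 0.26), the inducible nitric oxide synthase Nos2 (2.21 ± 0.25), the imprinted gene Mest (2.09 ± 0.17), the leukotriene C4 synthase Ltc4s (2.03) and the cholesterol exporter Abca1 (1.80). The 5 that fell were the sulfotransferase Sult1a1 (-1.26 ± 0.17), Dpysl5 (-1.02), Carmn (-0.83), Cyp2d22 (-0.74) and Mllt3 (-0.68). Among genes that did not pass, Cyp1a1, a target of the aryl hydrocarbon receptor, was lowest (-1.84, adjusted p = 0.14), with Abi3bp (-1.15), Hopx (-1.11), Kbtbd11 (-1.09) and the cobalamin carrier Tcn2 (-1.08). In all, 1319 genes had an unadjusted p under 0.05. The count was 0 (limma) without the control untreated, Kitl-deleted untreated, control bleomycin 2-week, control bleomycin 4-week or Kitl-deleted bleomycin 4-week library, with 569, 838, 644, 1143 and 1139 genes at an unadjusted p under 0.05. Leaving out the Kitl-deleted bleomycin 2-week library raised the count, with a single library left at that time. Without the 3 control libraries that stood apart, untreated and 2 weeks each keep a single Kitl-deleted library, so no count is given. With no expression filter and within gCap-like cells alone the count was also 0 (2392 and 1116 unadjusted).

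Among the fixed lists, 8 were higher at 2 weeks of bleomycin by camera with the preset correlation and none with an estimated one. In the extracellular matrix list 16 of 17 members were higher (median log2 0.83, 4 passed over all genes and 9 adjusted over the list alone, camera adjusted p = 1.5e-09, adjusted p = 0.43 with an estimated correlation). The 4 were Sparc, Sparcl1 and the basement membrane collagens Col4a1 (1.09) and Col4a2 (1.15), while Vwa1 (2.41) and Col18a1 (2.21), the source of endostatin, did not pass. In the tip cell and sprouting list 8 members were higher and 5 lower (median 0.70, 3 passed, 7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.58 with an estimated correlation), with the netrin receptor Unc5b at 1.07. Col4a1 and Col4a2 are members of this list as well, so the lists share genes and are not separate evidence. The interferon list was higher in 21 of 23 members (median 0.53, 1 passed, 14 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.1e-08, adjusted p = 0.43 with an estimated correlation). Its sensor Zbp1 rose by 1.34, and Rsad2 (1.01) and Ifit3 (1.01) did not pass. All 7 MHC class II members were higher (median 1.63, 0 passed over all genes and 7 adjusted over the list alone, camera adjusted p = 9.7e-08, adjusted p = 0.43 with an estimated correlation), led by Cd74 (3.15, limma adjusted p = 0.066), H2-Eb1 (1.76), H2-Aa (1.73) and H2-Ab1 (1.63). Within gCap-like cells alone the MHC class II median was 1.49, with 7 of 7 members higher (camera adjusted p = 5.1e-06, adjusted p = 0.71 with an estimated correlation), while the aCap-like share was 64.4% untreated and 35.7% at 2 weeks in control, and 66.3% and 53.4% in Kitl-deleted cells. The myeloid transcript Lyz2 was at 5.94 to 14.9 CPM and the leukocyte antigen Cd52 at 0.62 to 3.16 in all libraries. In the fibrosis-associated capillary list 16 of 17 were higher (median 0.87, 1 passed, 8 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.43 with an estimated correlation). The member that passed was Sparcl1, and Ntrk2 (2.69), Cmah (2.05) and Lrg1 (1.72) did not pass. In the hypoxia and glycolysis list 17 of 18 were higher (median 0.54, 1 passed, 12 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.47 with an estimated correlation). Ankrd37 passed, and Ndrg1 (1.48), the lactate dehydrogenase Ldha (1.13) and Hif1a (1.05) did not. The MHC class I list (median 0.34, 10 of 12 higher, 0 passed, 3 adjusted over the list alone, camera adjusted p = 0.0075, adjusted p = 0.87 with an estimated correlation) was led by H2-Q7 (0.56) and the peptide transporter Tap1 (0.56). The mesenchymal transition list (median 0.26, 6 of 6 higher, 0 passed, 2 adjusted over the list alone, camera adjusted p = 0.030, adjusted p = 0.43 with an estimated correlation) was led by Cnn2 (0.81). The medians in control and Kitl-deleted cells were 1.15 and 0.51 for the fibrosis-associated list and 0.78 and 0.29 for hypoxia, differences between genotypes that were not tested.

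At 4 weeks after bleomycin no gene passed the test (limma, 0 of 8360 genes, 676 with an unadjusted p under 0.05). Genes of MHC class II antigen presentation made up most of the highest values. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652, plus strand), was at 98.2 and 633 CPM in untreated and 4-week control cells and at 8.05 and 331 in Kitl-deleted cells (log2 3.66 ± 0.56 SE, limma adjusted p = 0.18). H2-Eb1 (2.26), H2-Aa (2.04), H2-DMb1 (1.78), H2-Ab1 (1.77) and H2-DMa (1.57) stood beside it, with Sparcl1 (1.83), Plac8 (1.81), Col18a1 (1.80) and Ntrk2 (1.48). The lowest were Cyp1a1 (-1.10), Lrrn3 (-1.08), Tbx3os1 (-0.88), Abi3bp (-0.86), Carmn (-0.84), Slc5a12 (-0.83), Dpysl5 (-0.82), Cyp4b1 (-0.81), Ms4a8a (-0.81) and the aerocyte marker Fibin (-0.79), and the aCap-like share was smaller as well (64.4% untreated and 43.9% at 4 weeks in control). Without either bleomycin 2-week library the count was 2, and with the file set term it was 57. Without the 3 control libraries that stood apart, untreated and 4 weeks each keep a single Kitl-deleted library, so no count is given.

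By camera with the preset correlation, 10 lists were higher at 4 weeks of bleomycin, with no member of any past the test over all genes. All 7 MHC class II members were higher (median log2 1.78, 7 adjusted over the list alone, camera adjusted p = 2.4e-14, adjusted p = 0.26 with an estimated correlation), and the median was 1.40 in control and 2.20 in Kitl-deleted cells, a difference that was not tested. The aCap-like share was 64.4% in the untreated and 43.9% in the 4-week control library, and 66.3% and 45.2% in Kitl-deleted cells. MHC class II genes were lower in aCap-like cells than in the unnamed clusters (by a median log2 of 2.191 to 4.203 in the bleomycin libraries). Within gCap-like cells alone the MHC class II median was 1.70, with 7 of 7 members higher (camera adjusted p = 3.9e-19, adjusted p = 0.41 with an estimated correlation). All 23 interferon members were higher (median 0.35, 8 adjusted over the list alone, camera adjusted p = 8.1e-11, adjusted p = 0.26 with an estimated correlation), with Zbp1 (1.01) and the interferon-induced GTPases Igtp (0.92) and Gbp4 (0.79). The immediate early and dissociation stress list was higher in 18 of 19 members (median 0.40, 0 adjusted over the list alone, camera adjusted p = 8.5e-08, adjusted p = 0.35 with an estimated correlation), with Fos at 0.89, Hspa1a at 0.87 and Fosb at 0.86. Matrix genes were higher in 15 of 17 (median 0.72, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.8e-07, adjusted p = 0.35 with an estimated correlation), with Vwa1 at 1.42 and Sparc at 1.24. The fibrosis-associated list had 14 of 17 higher (median 0.49, 1 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.38 with an estimated correlation). The MHC class I list had 10 of 12 higher (median 0.37, 4 adjusted over the list alone, camera adjusted p = 2.4e-05, adjusted p = 0.49 with an estimated correlation), with H2-Q6 at 0.78. The hypoxia list had 17 of 18 higher (median 0.25, 0 adjusted over the list alone, camera adjusted p = 1.8e-04, adjusted p = 0.49 with an estimated correlation), with Ankrd37 at 1.47. The tip cell list had 10 of 13 higher (median 0.44, 5 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.3e-04, adjusted p = 0.35 with an estimated correlation), with Trp53i11 at 1.07 and the aerocyte endothelin receptor Ednrb at -0.77. The mesenchymal transition list had 6 of 6 higher (median 0.28, 0 adjusted over the list alone, camera adjusted p = 4.9e-04, adjusted p = 0.26 with an estimated correlation). The p53 list had 18 of 19 higher (median 0.19, 0 adjusted over the list alone, camera adjusted p = 0.0062, adjusted p = 0.65 with an estimated correlation), with Gdf15 at 0.54 and Btg2 at 0.50.

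Removal of lung tissue is followed by growth of the remaining lung, and the early pneumonectomy libraries show the endothelium in that period. At this time 257 genes rose and 163 fell against untreated libraries (limma, 8360 genes, 2047 with an unadjusted p under 0.05). Mest, an imprinted gene on chromosome 6 (30723547 to 30748465, plus strand), rose by 2.24 ± 0.17 (log2, SE, adjusted p = 0.0047), and Sparc by 1.57 ± 0.15 (adjusted p = 0.0066). Plac8 (2.44 ± 0.33), Col18a1 (2.36 ± 0.50), Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (1.82 ± 0.29), Ifi27l2a (1.82), Tiam1 (1.80), Disp2 (1.65), the fatty acid binding protein Fabp5 (1.64) and the desaturase Scd2 (1.61) also rose. Sult1a1 fell by 2.33 ± 0.17 (adjusted p = 0.0047), with Fam212b (-2.27), Ttc39c (-2.16 ± 0.25), Lyve1 (-1.80), the p53 target Trp53inp1 (-1.77 ± 0.30), Fam107a (-1.59), Tcn2 (-1.53), the epoxide hydrolase Ephx1 (-1.52) and Ptpru (-1.51). Cdkn1a, the p53-induced inhibitor of the cell cycle (chromosome 17, 29090976 to 29100727, plus strand), fell by 1.47 ± 0.29 (adjusted p = 0.037). These differences cross the file sets, which cannot be told apart from the operation. The count was 0 (limma) without the control or the Kitl-deleted untreated library, with 988 and 1315 genes at an unadjusted p under 0.05. It was 115 without either bleomycin 4-week library, 272 with no expression filter (188 higher and 84 lower) and 2134 with the file set term (1128 and 1006). Leaving out either early pneumonectomy library lowered it, with a single library left at that time. Without the 3 control libraries that stood apart, untreated keeps a single library, so no count is given.

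Interferon genes made up 15 of the 257 risers in the early pneumonectomy libraries: 21 of 23 members were higher and 2 lower (median log2 0.90), and 19 passed adjusted over the list alone (camera adjusted p = 1.1e-11, adjusted p = 0.48 with an estimated correlation, fry adjusted p = 0.017). Zbp1 (1.44), Igtp (1.33) and Gbp4 (1.32) were highest after Ifi27l2a. In the matrix list 15 of 17 were higher (median 1.10, 7 passed, 12 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.55 with an estimated correlation, fry adjusted p = 0.046). The median was 0.67 in control and 1.31 in Kitl-deleted cells, and the Kitl-deleted library also held the fibroblast transcripts Col1a1 (33.9 CPM) and Col1a2 (28.3). The p53 list was lower in 16 of 19 members (median -0.84, 5 passed, 15 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.73 with an estimated correlation). Beside Trp53inp1 and Cdkn1a, the proapoptotic genes Pmaip1 (-1.05) and Bax (-0.84) and Ei24 (-0.71) fell, and Eda2r (-1.79), Gdf15 (-1.63) and Sesn2 (-1.55) did not pass. The median was -1.24 in control and -0.49 in Kitl-deleted cells, where the control untreated library is among the 3 that stood apart. MHC class II was higher in 7 of 7 (median 1.20, 2 passed, 6 adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.73 with an estimated correlation), through H2-DMa (1.20) and H2-DMb1 (1.20), which load peptides, and Cd74 at 2.29 did not pass. The MHC class II median was 0.60 in control and 1.98 in Kitl-deleted cells, where the Kitl-deleted untreated library held Cd74 at only 8.05 CPM, and this difference was not tested. The fibrosis-associated list had 14 of 17 higher (median 0.81, 3 risen and 1 fallen, 8 and 1 adjusted over the list alone, camera adjusted p = 7.0e-04, adjusted p = 0.73 with an estimated correlation). Those that rose were Emp1 (1.18), Cd34 (0.94) and Anxa2 (0.81), the fallen member was Cdkn1a, and Ntrk2 (1.82) did not pass. MHC class I was higher in 11 of 12 (median 0.34, 1 passed, 1 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.87 with an estimated correlation), with H2-T22 (0.58) past the test. The mesenchymal transition list was higher in 5 of 6 (median 0.51, 2 passed, 4 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.48 with an estimated correlation, fry adjusted p = 0.017), through the cytoskeletal genes Cnn2 (1.16) and Tpm1 (0.56). Camera called no shift of the tip cell list (8 of 13 higher, median 0.22, adjusted p = 0.157), the Notch list (8 of 12 lower, median -0.13, adjusted p = 0.228) or the TGF-beta and BMP list (11 of 17 lower, median -0.21, adjusted p = 0.318). Their medians in control and Kitl-deleted cells were -0.065 and 0.634, -0.275 and 0.048, and -0.211 and -0.059. Single members passed the test: Unc5b (1.36), Col4a1 (1.11), Col4a2 (1.04) and Cd34 (0.94) of the tip cell list rose, the last 3 of which are also in lists named above. Hey1 (-0.95) and Lfng (-0.56) of the Notch list and Id2 (-0.76), Smad7 (-0.62) and Bambi (-0.60) of the BMP list fell.

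Cell cycle genes were higher early after pneumonectomy, and most of the cells with several of their markers were gCap-like. Over all endothelial cells 6 of 7 proliferation genes were higher (median log2 0.48, 1 passed, 3 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.55 with an estimated correlation, fry adjusted p = 0.046), with the thymidylate synthase Tyms at 0.51. Within gCap-like cells 10 of 11 were higher (median 0.82, 5 passed, 8 adjusted over the list alone, camera adjusted p = 2.7e-07, adjusted p = 0.80 with an estimated correlation). Those that rose were the proliferation antigen Mki67 (3.35), the centromere protein Cenpf (3.19), topoisomerase Top2a (2.95), the mitotic ubiquitin enzyme Ube2c (2.58) and Tyms (0.82). Genes entered each fit by their mean over all 10 libraries, at least 10 CPM. Members high only in the early pneumonectomy libraries could pass that filter through them. The number of higher members, the median and the camera value may thus be partly set by the filter. At 2000 UMIs per cell, 88 of 1346 gCap-like cells (6.54%, 95% interval 5.28 to 7.99) carried at least 2 proliferation markers in the control early pneumonectomy library and 30 of 952 (3.15%, 2.14 to 4.47) in the Kitl-deleted library. Without thinning, at unequal depth, the shares were 13.8% and 6.21% in gCap-like cells and 3.66% (82 of 2238) and 1.02% (21 of 2060) in aCap-like cells. The genotype difference rests on 1 library each and was not tested, since the intervals cover counting error only. The control bleomycin 2-week library reached 0.996% (0.545 to 1.67), and the other 7 were at or below 0.489%, with 0 of 1617 cells in the Kitl-deleted untreated library (95% interval up to 0.228%). At 2000 UMIs, where fewer markers are seen, the Kitl-deleted bleomycin 4-week library had 0 of 1931 cells, against 6 of 1954 (0.307%) without thinning. In aCap-like cells the thinned share was at most 0.134% in any library.

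**Figure D3:**
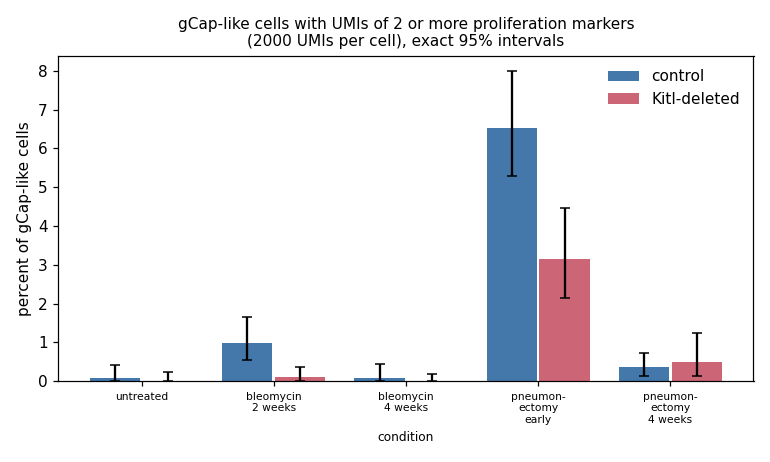
Share of gCap-like cells (y axis, percent) with UMIs of at least 2 proliferation markers at 2000 UMIs per cell by condition (x axis) and genotype, with 1 library per bar and exact 95% Clopper-Pearson intervals as error bars. The early pneumonectomy libraries reached 6.54% in control and 3.15% in Kitl-deleted cells, and no other library was above 0.996%.

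At 4 weeks after pneumonectomy 12 genes rose and 11 fell against untreated libraries (limma, 8360 genes, 1297 with an unadjusted p under 0.05). Mest was highest (log2 1.41 ± 0.17 SE, adjusted p = 0.034), followed by Unc5b (1.03 ± 0.12, adjusted p = 0.034), Dpysl3 (0.93), the calcineurin regulators Rcan3 (0.88) and Rcan1 (0.82), Ddah1, which degrades an inhibitor of nitric oxide synthase (0.88), the endothelial repressor Bcl6b (0.85), Snx18 (0.81), the kinase Pkn3 (0.81) and the G protein Gnai1 (0.80). Ttc39c (-2.06), Sult1a1 (-1.96 ± 0.17, adjusted p = 0.033), Dcxr (-1.59), the Notch target Hey1 (-1.26 ± 0.14, adjusted p = 0.034), Snhg9 (-1.07), xanthine dehydrogenase (Xdh, -1.06), the proapoptotic p53 target Bax (-0.98 ± 0.13, adjusted p = 0.042), Serinc3 (-0.93), the muscarinic receptor Chrm2 (-0.79) and Carmn (-0.76) fell. The p53 list was lower in 17 of 19 members (median -0.90, 1 passed, 13 adjusted over the list alone, camera adjusted p = 6.8e-13, adjusted p = 0.87 with an estimated correlation). Sesn2 (-1.95), Gdf15 (-1.82), Trp53inp1 (-1.77) and Cdkn1a (-1.77) did not pass over all genes, and the median was -1.12 in control and -0.64 in Kitl-deleted cells. MHC class II was higher in 7 of 7 (median 1.36, 0 passed, 6 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.87 with an estimated correlation), with Cd74 at 2.56 and H2-Aa at 1.61. The matrix list was higher in 14 of 17 (median 0.57, 0 passed, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.93 with an estimated correlation), with Fbln2 at 1.33 and Col15a1 at 1.08. These differences also cross the file sets. The count was 0 (limma) without the control untreated, Kitl-deleted untreated or Kitl-deleted pneumonectomy 4-week library, with 473, 814 and 1629 genes at an unadjusted p under 0.05. It was 1 without either bleomycin 4-week library, 2 without either early pneumonectomy library and 0 with no expression filter (limma, 2458 at an unadjusted p under 0.05). Leaving out the control pneumonectomy 4-week library also lowered it, with a single library left at that time. Without the 3 control libraries that stood apart, untreated keeps a single library, so no count is given.

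The pneumonectomy times were also compared within their own file set, a test chosen after the data had been seen. With the file set term 23 genes were higher early than at 4 weeks and 7 lower (limma, 1219 with an unadjusted p under 0.05). The higher ones included the interferon-induced genes Isg15 (log2 1.14), Igtp (0.95), Irgm1 (0.78), Irgm2 (0.72) and Rnf213 (0.71), the antigen presentation genes Tap1 (0.84) and Nlrc5 (0.69), and the matrix genes Mmp14 (0.90), Col4a1 (0.83) and Col4a2 (0.78). The nuclear lamin Lmnb1 (0.82) and cyclin D1 (Ccnd1, 0.54) were higher too. The lower ones were Kank4 (-0.84), the thioredoxin inhibitor Txnip (-0.72), Lncpint (-0.68), Zfp503 (-0.63), Jade1 (-0.61), Cbx7 (-0.61) and Cyp2d22 (-0.60).

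Bleomycin and pneumonectomy were compared as the mean of their time points, which asks how fibrotic injury and regrowth differed. Relative to pneumonectomy 123 genes were higher after bleomycin and 104 lower (limma, 8360 genes, 1855 with an unadjusted p under 0.05). In the p53 and DNA damage list 18 of 19 members were higher (median log2 0.91), 13 passed over all genes and 16 adjusted over the list alone (camera adjusted p = 8.8e-16, adjusted p = 0.84 with an estimated correlation). Sesn2 (2.04 ± 0.36 SE, adjusted p = 0.036), Eda2r (2.02 ± 0.32, adjusted p = 0.026), the stress cytokine Gdf15 (1.94 ± 0.29, adjusted p = 0.023), Trp53inp1 (1.68) and Cdkn1a (1.36) were among them. Cdkn1a was at 1170 to 1983 CPM in control untreated and bleomycin libraries, 759 to 1041 in the Kitl-deleted ones and 400 to 522 in the pneumonectomy libraries. Fam212b (2.12), the serpins Serpina3n (2.00) and Serpina3m (1.85), Dcxr (1.66), the mitophagy receptor Bnip3 (1.53 ± 0.25) and Ankrd37 (1.49) were also higher, as were Sparcl1 (1.48) and Hey1 (1.14). Cyp1a1 was lowest after bleomycin (-2.87 ± 0.35, adjusted p = 0.015), with Tekt5 (-0.99), the cytokine Il1a (-0.92), Col12a1 (-0.87), Crip1 (-0.86), Runx1t1 (-0.82), the isoprenoid enzyme Fdps (-0.78), Sap18b (-0.76), Rcan3 (-0.73) and Hlx (-0.73). File set and treatment cannot be told apart here. The count was 63 without the control and 64 without the Kitl-deleted untreated library, and 38 without the control bleomycin 2-week library. It was 1 and 10 without the control and Kitl-deleted bleomycin 4-week libraries and 29 without the control early pneumonectomy library. Without the control and Kitl-deleted pneumonectomy 4-week libraries it was 23 and 112. Without the 3 control libraries that stood apart, each bleomycin time keeps a single Kitl-deleted library, so no count is given. More genes were lower than higher with no expression filter (24 higher and 65 lower) and with the file set term (869 and 1039).

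Of the other lists, hypoxia and glycolysis was higher after bleomycin in 16 of 18 members (median log2 0.29, 2 passed, 3 adjusted over the list alone, camera adjusted p = 5.5e-04, adjusted p = 0.84 with an estimated correlation), through Bnip3 and Ankrd37. The immediate early and dissociation stress list was higher in 14 of 19 (median 0.36, 1 passed, 6 adjusted over the list alone, camera adjusted p = 7.7e-04, adjusted p = 0.84 with an estimated correlation), through Btg2 (0.62), an antiproliferative gene also in the p53 list, and Hspa1a (1.13), Fos (0.75) and Fosb (0.75) did not pass. MHC class I was higher in 11 of 12 (median 0.13, 1 passed, 2 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.84 with an estimated correlation), with H2-Q7 at 0.51. MHC class II was higher in 7 of 7 (median 0.39, 0 passed and 0 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.84 with an estimated correlation). The fibrosis-associated list was higher in 12 of 17 (median 0.14, 2 passed, 4 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.84 with an estimated correlation), through Sparcl1 and Cdkn1a, and Lrg1 (1.84) did not pass. Oxidative phosphorylation was lower in 22 of 26 members (median -0.09, 0 passed, camera adjusted p = 0.047, adjusted p = 0.84 with an estimated correlation), with the respiratory chain subunits Ndufb8 at -0.26 and Cox5a at -0.25.

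**Figure D4:**
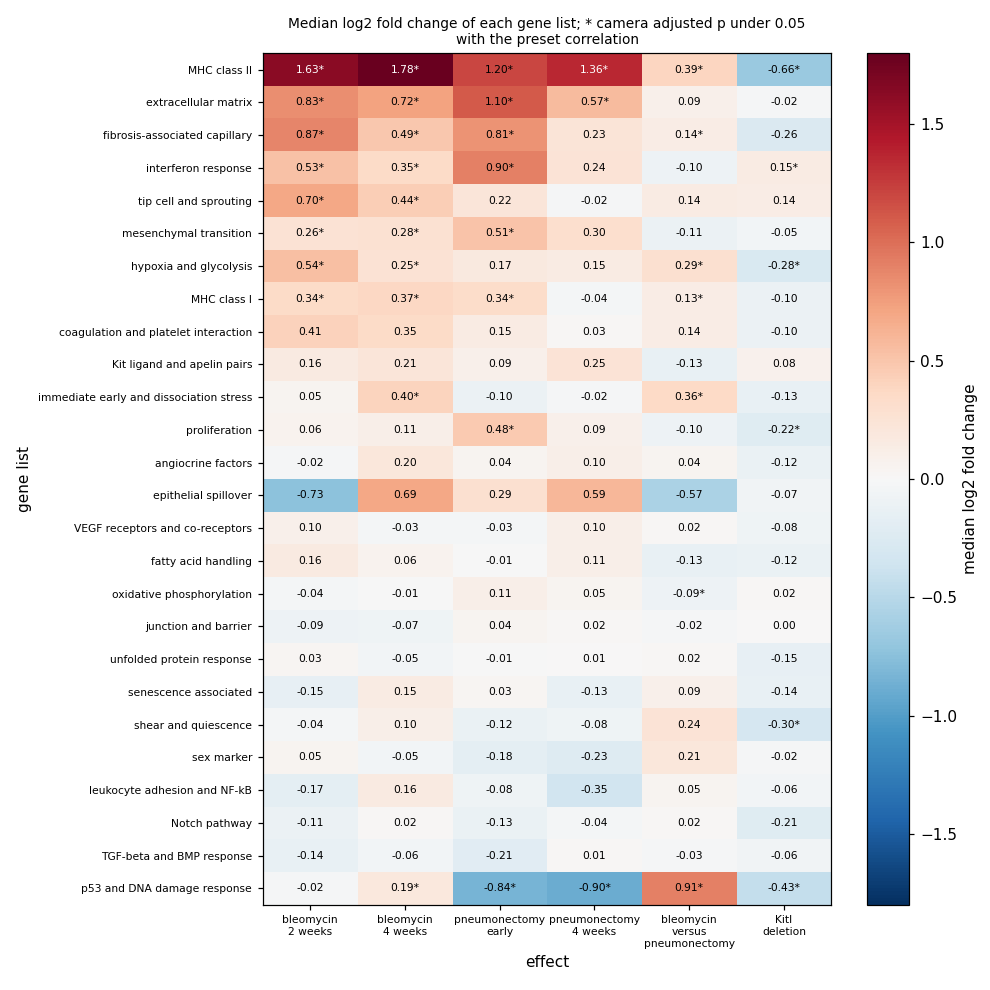
Median log2 fold change (colour and number) of each tested gene list (y axis) for the 6 effects (x axis), with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. MHC class II had the highest medians after bleomycin (1.63 and 1.78), and the p53 list was lower in both pneumonectomy columns (-0.84 and -0.90).

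**Figure D5:**
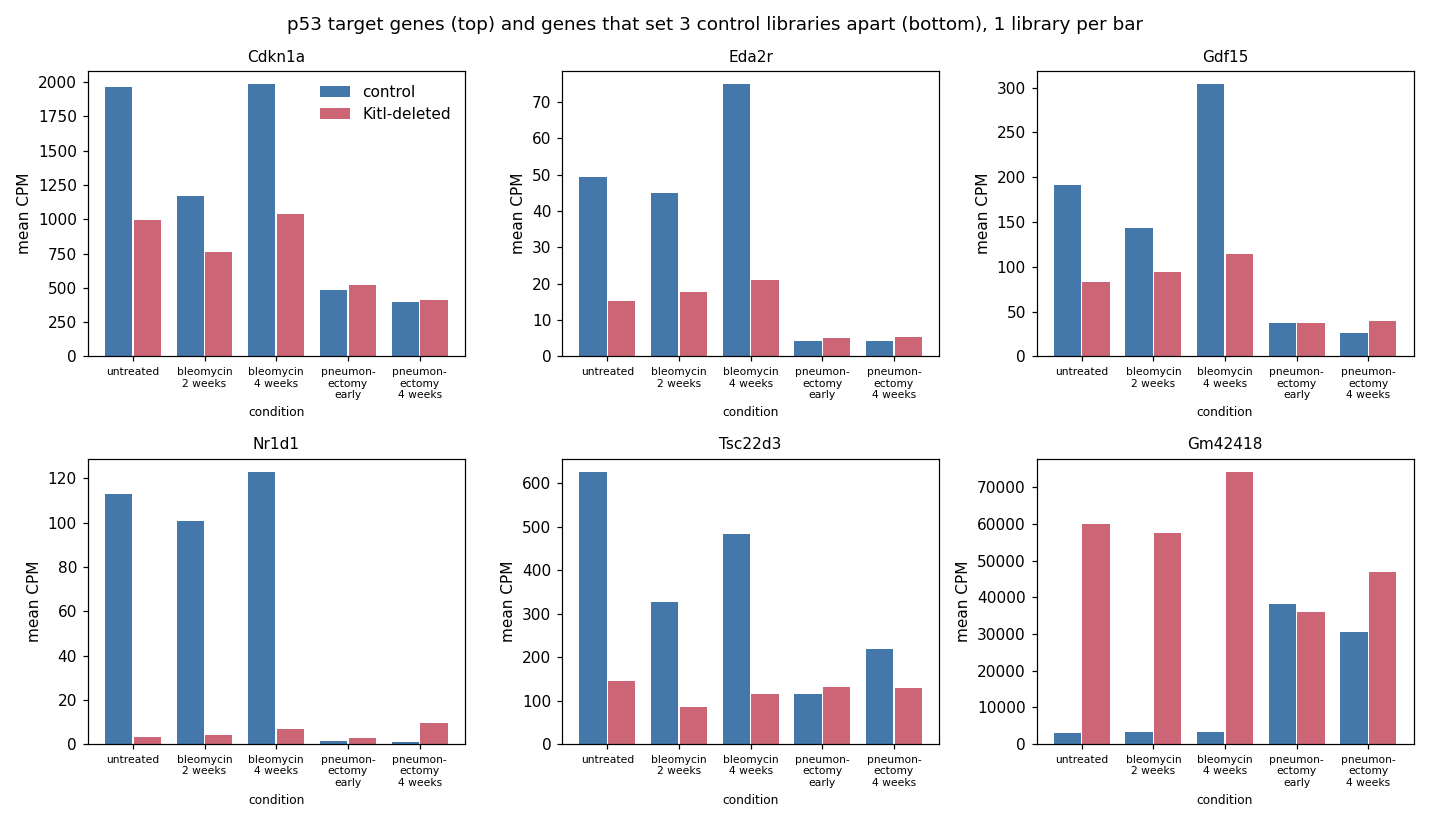
Mean level in CPM (y axes) of the p53 targets Cdkn1a, Eda2r and Gdf15 (top) and of Nr1d1, Tsc22d3 and Gm42418 (bottom) by condition (x axes) and genotype, with 1 library per bar and no error bars. The p53 targets were lowest in the 4 pneumonectomy libraries, and the bottom genes set the control untreated and bleomycin libraries apart from the other 7.

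The remaining 13 lists passed camera in none of the 6 effects (lowest camera adjusted p = 0.054, for coagulation at 2 weeks of bleomycin). Over the effects their medians ran from -0.13 to 0.25 for Kit ligand and apelin pairs (3 genes), -0.08 to 0.10 for VEGF receptors (10), -0.21 to 0.02 for the Notch pathway (12), -0.12 to 0.20 for angiocrine factors (17) and -0.21 to 0.01 for TGF-beta and BMP response (17). They ran from -0.35 to 0.16 for leukocyte adhesion and NF-kB (9), -0.15 to 0.15 for senescence (10), -0.13 to 0.16 for fatty acid handling (13), -0.15 to 0.03 for the unfolded protein response (13) and -0.10 to 0.41 for coagulation and platelet interaction (10). Junction and barrier genes ran from -0.09 to 0.04 (19), sex markers from -0.23 to 0.21 (4) and epithelial spillover genes from -0.73 to 0.69 (3). The haemoglobin transcript Hbb-bs was at 61.1 CPM in the control bleomycin 2-week library, 157 in the control early pneumonectomy library and at most 17.8 elsewhere.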

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

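The test of the Kitl deletion difference between file sets and the tests of genotype and of the time of preparation below were chosen only after the result was seen.

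The difference between Kitl-deleted and control libraries differed between the file sets for 1820 genes (1236 higher and 584 lower in the pneumonectomy files, limma with a file set term, adjusted p under 0.05). Among them were Nr1d1 (log2 4.39), Zbtb16 (3.07), Fkbp5 (2.88), Dbp (2.63), Tef (2.52), Tsc22d3 (1.71), Arntl (-1.12), Lars2 (-2.85), AY036118 (-3.65) and Gm42418 (-4.03). Kitl itself differed by -0.02 (adjusted p = 0.917) and Hebp1 by -0.70 (adjusted p = 0.272). Clock and glucocorticoid genes, and also Gm42418, AY036118 and Lars2, set the 3 control untreated and bleomycin libraries apart: the glucocorticoid target Fkbp5 was at 29.9 to 49.7 CPM against 1.54 to 5.19 in the other 7 libraries and the clock factor Arntl at 3.52 to 5.62 against 15.1 to 18.1.

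The clock and glucocorticoid genes differed in those 3 libraries by a median log2 of 1.645. For this median the sign was turned for Arntl, Clock and Cry1, which are opposite in phase to Nr1d1. A different mix of cell classes is argued against on this scale only, since within gCap-like cells the median was 1.474, 89.6% of that over all cells. That gCap-like median is the turned value of Arntl (-1.474), so the share rests on the choice of sign. An effect of Kitl genotype alone is argued against too, since the control minus Kitl-deleted median in the pneumonectomy pairs was 2.8% of the difference. Preparation at another time of day is a candidate explanation, since 10 of 11 measured clock genes went the way of their phase, although of the 3 of opposite phase Arntl was clearly lower (-1.10), Clock was nearly flat (-0.015) and Cry1 was higher (0.50). The labels give no preparation date, so a stress response of the animals, a batch, or other library preparation or read counting, to which the lower Gm42418, AY036118 and Lars2 also belong as untested, stay open, as does a genotype effect limited to these conditions.

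Other groupings of the samples bear on the 2 genes called for Kitl deletion. Swapping genotype within conditions allows 16 splits, too few for a share under 0.05, and the real one called 2 genes and the highest other 0. Among 100 of the 126 splits of the libraries into 5 against 5, 3 called at least as many genes, a share under 0.05, but these splits ignore the matching by condition and so do not settle whether chance alone gives 2 genes. The highest other split called 2893 genes and set the 3 control untreated and bleomycin libraries with both early pneumonectomy libraries against the rest. With condition in the fit, that split contrasts the genotypes within the untreated and bleomycin pairs alone. It thus repeats the genotype difference of those files and cannot show a structure of the samples other than genotype. Within the file sets the counts were 4 genes (pneumonectomy) and 3453 (untreated and bleomycin).

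Tip cell and sprouting genes at 4 weeks after pneumonectomy had a median log2 of 0.413 against untreated in Kitl-deleted cells (10 of 13 higher) and -0.263 in control cells (9 of 13 lower), and the difference between genotypes was not tested. MHC class I genes at the same time had a median of 0.234 in Kitl-deleted cells (10 of 12 higher) and -0.376 in control cells (12 of 12 lower), and the difference was likewise not tested. Both control values are taken against the control untreated library, which is among the 3 that stood apart, and other lists split alike at this time: the dissociation stress list had medians of 0.084 in Kitl-deleted and -0.354 in control cells, and the epithelial spillover list 1.117 and -0.186. Neither split is thus specific to its list. No group held the 4 samples needed for an outlier test.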

How the results depend on the processing

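The file set term, the fits without the unnamed clusters or without the 3 control untreated and bleomycin libraries, and the tests of Kitl deletion within a file set were chosen only after the result was seen. The main counts were 48 genes for bleomycin at 2 weeks, 0 for bleomycin at 4 weeks, 420 for early pneumonectomy, 23 for pneumonectomy at 4 weeks, 227 for bleomycin versus pneumonectomy and 2 for Kitl deletion. A pseudocount of 1 or 20, summed UMIs, no intensity trend, cells with at least 1000 genes and leaving out the unnamed clusters kept each count within 1.5 times, while all barcodes or Leiden 0.5 leave the fits over all endothelial cells as they are, since every cluster counted as endothelial, and the counts within classes were not rerun at Leiden 0.5. With no expression filter the counts were 0 (2392 at an unadjusted p under 0.05 in limma) for bleomycin at 2 weeks, 272 for early pneumonectomy, 0 (2458 unadjusted) for pneumonectomy at 4 weeks, 89 for bleomycin versus pneumonectomy and 1 for Kitl deletion, where more genes are tested. Median centring, which shifted no effect by more than log2 0.048, gave 25 for bleomycin at 2 weeks, and 10 up and 17 down against 12 and 11 for pneumonectomy at 4 weeks. In gCap-like cells alone the counts were 0 (1116 unadjusted) for bleomycin at 2 weeks, 110 for bleomycin versus pneumonectomy and 1 for Kitl deletion. In aCap-like cells alone they were 87 for bleomycin at 2 weeks, 37 for pneumonectomy at 4 weeks, 95 for bleomycin versus pneumonectomy and 5 for Kitl deletion. With the file set term they were 833, 57, 2134, 918, 1908 and 2420 in the order of the main counts, and without the 3 control libraries 123, 150, 1143, 297, 783 and 31. The counts without the 3 control libraries are listed only as a record of the setting, and no conclusion is drawn from them. In that fit untreated and each bleomycin time keep a single Kitl-deleted library. Its Kitl deletion contrast rests on the pneumonectomy pairs alone. For this reason the Results do not give these counts beside the effects. Kitl deletion gave 4 genes within the pneumonectomy files and 3453 within the others. With each library left out in turn the counts ran from 0 to 264, 0 to 2, 0 to 456, 0 to 18, 1 to 315 and 2 to 109. The causes of these shifts were not tested. Gene list calls went from 42 to 0 with an estimated correlation. The venous-like share difference reversed from -0.218 to 0.227 points at Leiden 0.5. Named genes were followed with a pseudocount of 1, median centring, gCap-like cells alone and each library left out, and none that was measured reversed its sign, but 16, 13, 19, 19, 15 and 16 of 20 per effect were measured in gCap-like cells. These genes were chosen for the same sign in both genotypes, or in at least 4 of 5 conditions for Kitl deletion. Their sign with a library left out was thus largely set in advance and is not separate evidence. In the order of the main counts, 4, 0, 2, 3, 0 and 0 called named genes no longer passed with median centring, 12, 0, 5, 9, 6 and 1 in gCap-like cells alone, and 81, 0, 87, 172, 99 and 0 gene and library cases with a library left out. No paired analysis was possible because the labels pair no animals, and condition, the only matching of libraries, is already in the fit. Scrublet called 0.031 to 1.40% of cells per library. Depth limits genes near the floor of 0.116 CPM.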

Other observations

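The file set test, the test of 1 mixing share, the joining of new clusters and the stress test against aCap-like cells below were chosen only after the result was seen.

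Cells with several marker levels between those of both main capillary classes made up a larger share of the bleomycin libraries. Clusters 1 (1125 cells) and 6 (677 cells) were led by Ankrd37, Bnip3, Ntrk2, Adora2a and Nos2. Together they held 9.99 ± 4.01% of cells in the 4 bleomycin libraries and 0.893 ± 0.506% in the other 6 (SD). No p-value is given for this contrast, since it was chosen after the clusters were seen. In the bleomycin libraries these cells carried the aerocyte carbonic anhydrase Car4 at 1075 to 1250 CPM, between gCap-like (81.4 to 152) and aCap-like cells (2731 to 3278), and Gpihbp1 at 847 to 1230. Kit was at 7.87 to 111 CPM and the fenestral diaphragm gene Plvap at 13.5 to 143, against 864 to 1417 in gCap-like cells. The hypoxia-induced peptide Adm was at 23.4 to 111, Nos2 at 72.6 to 127, Sparcl1 at 1096 to 2044 and tdTomato at 1995 to 4619 CPM. For tdTomato the aCap-like level was 1990 to 4535 CPM and the gCap-like level 270.5 to 449. Sparcl1 lay above both classes in each library (12.5 to 26.6 CPM in aCap-like and 365.5 to 1308 in gCap-like cells). The hypoxia list lay above gCap-like cells by a median log2 of 0.28 to 0.59 and above aCap-like cells by 0.97 to 1.44, while MHC class II lay below gCap-like cells (-2.38 to -0.61). Their median depth was 6979 to 9706 UMIs.

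Stress of gCap-like cells during dissociation is argued against as the source of these unnamed cells. The stress list's highest median over the 4 libraries was -0.106 against gCap-like cells. Stress of aCap-like cells stays open, since the list lay above those by 0.449 to 1.298. MHC class II also lay above aCap-like cells, by 2.191 to 4.203, and Gpihbp1 was at 847 to 1230 against 80.5 to 208 CPM. The stress list does not cover these differences. Doublets of gCap-like and aCap-like cells stay open: 5 genes (Bnip3, Nos2, Adora2a, AA467197 and Adm) lay more than 2-fold above both classes in each library, short of the 10 set to exclude doublets, and the share of gCap-like genes more than 2-fold off 1 common mixing share was 57.3, 54.4, 13.6 and 17.5% (control 2 and 4 weeks, Kitl-deleted 2 and 4 weeks), so the libraries split. Scrublet called 10.78% of the unnamed cells in the Kitl-deleted 2-week library, where their median depth was above that of gCap-like cells (9706 and 8815 UMIs), and 0.37 to 1.05% in the other 3, where it was below. Clustering again without 276 genes called after bleomycin or leading these clusters gave a best Jaccard index for 1 new cluster of 0.4798 to 0.5121 over 6 seeds, which does not decide, but the new clusters made up mostly of unnamed cells, joined, gave 0.7328 to 0.8033, which argues against those genes alone as the source. Among aCap-like genes tdTomato lay near the aCap-like level (1995 to 4619 against 1990 to 4535 CPM), while Ednrb was at 225 to 333 against 1448 to 1768. Whether the aCap-like genes lie at 1 mixing share was not tested. A capillary state after injury may be another source, and no test here separates it from doublets.

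The p53 and DNA damage list was lower in all pneumonectomy libraries than after bleomycin, with a median log2 difference of 0.905. Different cell filters in the file sets are argued against, since a common range of 1004 to 4986 genes per cell left a median of 0.903. A different class mix is argued against too, with 1.288 within gCap-like cells and 0.819 within aCap-like cells. Bleomycin minus untreated gave 0.109 and untreated minus pneumonectomy 0.875 (17 of 19 higher), so the larger difference goes with the file sets, although within the untreated and bleomycin files the list also differed between genotypes (medians of -0.83 to -0.72). The file set and a biological effect of pneumonectomy cannot be told apart, since no untreated library shares the pneumonectomy file set.

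For bleomycin versus pneumonectomy, a fit with 3 levels called 328 genes for the real split of the 8 treated libraries, and the highest of the other splits called 0. Of 35 splits 1, the real one, called as many, the smallest share that 35 splits allow, but the splits ignore the matching by genotype and time and the real one also follows the file sets, so they do not settle whether the treatment gave this count. Without the control bleomycin 4-week library the count of 227 in the additive fit was 1.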
